A study of Homo sapiens with 2 samples.

How the data were processed

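Total RNA of 2 cultures of SH-SY5Y neuroblastoma cells that express the murine ecotropic receptor was measured on Illumina BeadChips with biotin-labelled RNA, per the labels' protocols. 1 culture had been infected with an MSCV retrovirus carrying ZNF423 and 1 with the vector alone. Each group held 1 array, so nothing could be averaged, no test was run and no p-value is given. The labels call the experiments representative, and other runs are not analysed here.

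The deposited scanner tables give, per the file headers, a signal intensity and a detection p for each of 49576 probes per array. The intensities were used as deposited, and their values show no background subtraction. Their sums over gene probes, 24994142 on the control array and 25007819 on the array labelled ZNF423, nearly match, as scaling to a common mean would give, so such scaling before deposit is not excluded. Their upper quartiles differ (159.8 and 183.8), so quantiles were not equalised, and "no normalization" here means none beyond the deposited values. The scanner software is not given in the sources used here. The detection p is the rank of a probe among the negative control probes of its array, as its steps show. Median signals were 99.97 on the vector control array and 99.69 on the array labelled ZNF423, and negative controls had medians of 87.5 and 87.2, so the median gene probe lies near background. A second table holds the authors' processed values on a log2-like scale, with column medians of 6.92 and 6.93. Per the labels and the submitters' processing notes, lumi and limma were used by the authors. Versions, the transformation and any normalization between arrays are not given in the sources used here. Each column of that log2 table ranks the probes exactly as its own array's signal does (Spearman correlation 1), so its columns belong to the arrays they name. Its differences correlated with the main differences at a Pearson r of 0.977 across detected probes, with a slope of 0.71, so the table gives smaller differences. It served as an alternative, and its exact scale and centring stay unknown.

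From the intensities, background was removed by normexp with the negative control probes and an offset of 16, followed by quantile normalization of the 2 arrays and log2, with limma 3.58.1 in R 4.3.3. Quantile normalization gives both arrays one distribution, so a shift of all genes together cannot be seen. The 773 control probes per array were then left out, which leaves 48803 gene probes. The negative controls were recognised from the steps of the detection p. Gene names came from the platform annotation supplied for the value table: 27578 probes had 1 symbol, 13 had several and 21212 had none, and probes without a single symbol were left unnamed. Entrez identifiers of 27541 probes matched the gene table of the GRCh38.p14 assembly, which was used for names and gene spans only, and 0 symbols needed an update beyond those of the annotation supplied. The 18665 named genes took the value of the probe with the highest mean over both arrays. A gene was detected if any of its probes had a detection p under 0.01 on at least 1 array. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 did the counting, statsmodels 0.14.6 the trend on gene span, and matplotlib 3.10.9 the figures.

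Differences are the array labelled ZNF423 minus vector control in log2 units, and a gene counted as higher or lower at 1 log2 unit (2-fold). A gene not detected on one array has only a bound. It is given as "at least N-fold", with the dim side set at the higher of its own level and the lowest level of a detected probe on that array, and no fold is given where that bound is below 1. Counts of higher and lower members use the measured differences, and the counts at the bounds are given beside them where they differ for a list. For each of 34 gene lists, the median difference of its detected members was ranked among the medians of 10000 random lists of the same size, drawn from detected genes matched in 10 bins of mean level. Lists with under 3 detected members have no median. A percentile describes these 2 arrays and is not a p-value, since members are not independent replicates. About 1 list in 20 would lie outside the central 95% by chance if members varied independently. Where members vary together, more lists would. The lists, the counting rule and the naming rule were fixed before the data were examined. The text names ZNF423, the 15 genes with the highest and the 15 with the lowest difference among detected genes with 1 symbol, and up to 4 detected members of each list with the largest absolute difference. Other genes are named only with a statement that they were chosen after their values were seen.

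The counting and list steps were tested on simulated data. A pair of arrays was drawn from the control array's corrected signals, with probes undetected at 0.05 given background only, noise of 0.2 log2 units per array and 200 genes changed by known amounts. Over 10634 detected genes, 88.0% of genes raised by 1.5 log2 units and 90.0% of those lowered by as much were counted, with median differences of 1.37 and -1.36. All genes changed by 3 log2 units were counted on the right side (100%), with medians of 2.86 and -2.70. Of 10406 unchanged genes 98 (0.94%) passed 1 log2 unit. A list shifted by 0.6 gave a median of 0.57 at percentile 100, and 3 of 33 lists left unshifted fell outside the central 95%. The noise level was assumed, so these rates describe the steps and not the error of the real cultures.

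Alternatives were another detection threshold, detection on both arrays, no detection filter, no normalization, median centring, loess, an offset of 50, the mean of detected probes, each probe on its own, the authors' value table, sizes of 1.5-fold and 3-fold, unmatched random lists and the mean over members. No background correction, bounds for undetected sides and removal of a trend on gene span were chosen after seeing the data.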

Results

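RNA of SH-SY5Y cells, a human neuroblastoma line of sympathetic neuronal origin, was profiled on 2 Illumina BeadChip arrays. The cells carried the murine ecotropic receptor, which lets mouse retroviruses enter. 1 array held RNA of cells infected with an empty MSCV retroviral vector, and 1 array held RNA of cells infected with the same vector carrying ZNF423, a zinc-finger transcription factor. Each array gave 48803 gene probes. On the vector control array 11693 probes (24.0%) were detected at a detection p under 0.01, and on the array labelled ZNF423 13066 (26.8%) were. With 1 array per group there was no replicate error and no test, and the number of arrays limits the precision of every value. The differences below describe these 2 arrays and carry no p-value. As a measure of error within an array pair, different detected probes of one gene differed between the arrays with an SD of 0.38 log2 units over 2109 genes, and the negative control probes with an SD of 0.15.

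The level of ZNF423 itself checks the labels. The array held 2 ZNF423 probes, both assigned to the transcript NM_015069, and they went opposite ways. Probe ILMN_1763602 read 162.9 on the vector control array, where it was not detected at 0.01 (detection p 0.0119), and 425.1 on the array labelled ZNF423. Set against the lowest detected level of the control array, that is at least 2.80-fold higher. Probe ILMN_2154950 was detected on both arrays and read 578.6 and 473.8, a normalized log2 difference of -0.74, or 1.67-fold lower. Where each probe lies relative to the part of ZNF423 carried by the vector is not used here, so a probe outside that part would check nothing. Because 1 probe goes against the label, the second array is called "the array labelled ZNF423" throughout, and every direction given here rests on that label. The gene value chosen by the brightest-probe rule was -0.74, and the mean of both probes was 0.44.

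The comparison asks which genes differ in level between ZNF423-infected and control cells. Of 9155 genes detected on at least 1 array, 1074 (11.7%) were higher by at least 1 log2 unit on the array labelled ZNF423 and 1003 (11.0%) were lower. The other 7078 lay in between. These counts and the differences of single genes keep the trend with gene span given below, which was removed for list medians only. The lower side reached further. Differences of at least 2 log2 units were seen for 78 genes higher and 200 lower, and of at least 3 log2 units for 11 higher and 75 lower. With each undetected side raised to the lowest detected level of its array, 776 genes were higher and 906 lower. Of the genes counted, 51.7% were higher. This share was 78.7% without normalization between the arrays, 38.0% after median centring and 41.4% after loess. The median of all genes was 0.03 in the main values, 0.28 without normalization and -0.15 after median centring, and changes are best read relative to those medians.

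**Figure D1:**
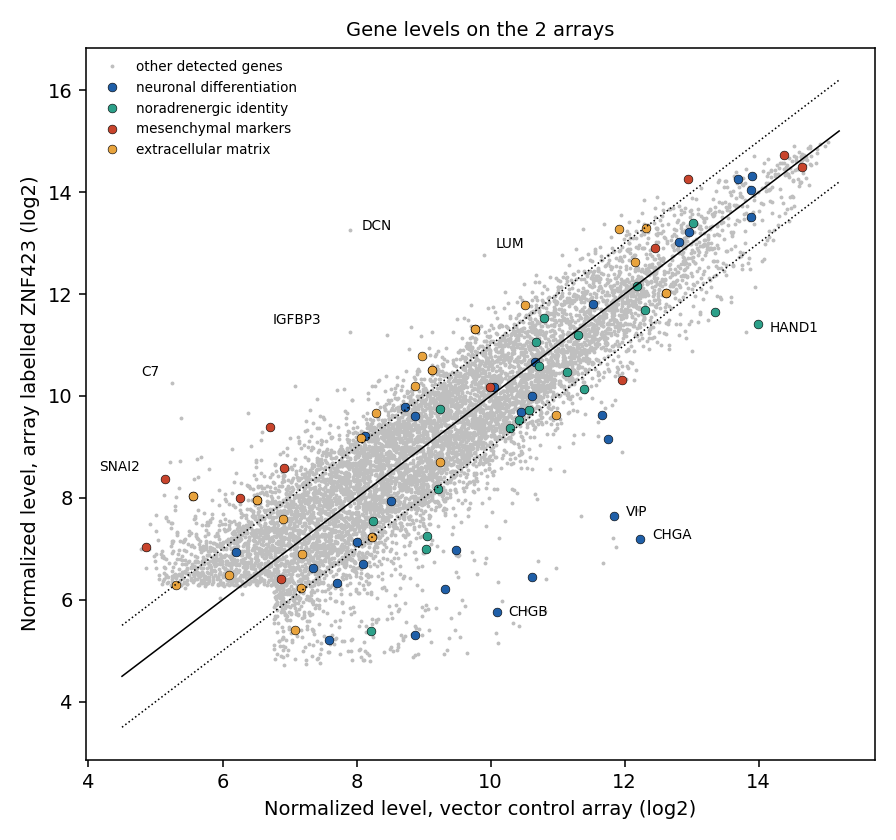
Normalized log2 level of each detected gene on the vector control array (x axis) and on the array labelled ZNF423 (y axis), 1 point per gene and 1 array per axis. Coloured points are detected members of 4 gene lists, the solid line marks equal levels and the dotted lines 1 log2 unit of difference; DCN lies farthest above the line, at a difference of 5.35, and CHGA farthest below it, at -5.04.

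The 15 highest differences began with DCN. This gene, which encodes the matrix proteoglycan decorin, was 5.35 log2 units higher, and the 2 of its 4 probes that were detected gave 4.62 and 5.35. The related proteoglycan gene LUM was 2.85 higher, with 1.14 at its other probe, THBS2, a thrombospondin, 3.13 higher and IGFBP3, an insulin-like growth factor binding protein, 3.34 higher. The remaining genes among the 15 highest were not detected on the control array and have only bounds. Both sets of 15 were ranked on measured differences, and with undetected sides at their bounds 7 of the 15 highest and 10 of the 15 lowest would be named again. C7, a complement component, was at least 11.2-fold higher, the WNT antagonist DKK2 at least 7.53-fold and LRRC17 at least 7.03-fold. The receptor S1PR3 was at least 4.58-fold higher, RIT2 at least 4.14-fold, PTPN14 at least 3.99-fold, NECAB2 at least 3.91-fold and PLCXD3 at least 3.87-fold. SNAI2, a transcription factor of epithelial to mesenchymal transition, was at least 3.04-fold higher, NRP1, a semaphorin and VEGF co-receptor, at least 2.71-fold at its brightest probe and SLC16A4 at least 2.46-fold. The other detected NRP1 probe gave a smaller measured log2 difference of 1.25.

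The 15 lowest differences began with CHGA. This gene, which encodes the neurosecretory granule protein chromogranin A, differed by -5.04 log2 units (32.8-fold lower). NNAT gave -4.94 (-3.86 at its other detected probe), TLCD3B -4.62, and the neuronal genes NSG2 -4.43 and SEZ6L2 -4.41 (-3.27 at its other detected probe). Undetected on the array labelled ZNF423 were the potassium channel gene KCNT1, at least 23.1-fold lower, the sodium/calcium exchanger gene SLC8A3, at least 14.3-fold lower, and ACTL6B, a subunit of the neuronal BAF chromatin remodelling complex, at least 17.7-fold lower. CKMT1A was at least 18.9-fold lower, and its near-identical copy CKMT1B cannot be told from it by this probe. TSPAN18 was at least 16.7-fold lower, FABP6 at least 13.9-fold, RUNDC3A at least 10.4-fold, RGS16 at least 8.45-fold and CD24 at least 8.19-fold. COX17, a copper chaperone of cytochrome oxidase measured by 1 probe, gave -4.84.

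Genes of neuronal differentiation were lower as a group. Of 30 detected members 12 were lower by at least 1 log2 unit, 2 were higher and 16 lay in between, and the median of -0.67 stood at percentile 0.03 of 10000 random lists matched on level. Next to CHGA, the granule protein gene CHGB was at least 14.1-fold lower, the neuropeptide gene VIP gave -4.21 (18.4-fold lower) and INA, a neuronal intermediate filament, -4.16. Not all members went this way: NCAM1 gave 1.06, SYT1 1.09, GAP43 0.74 and STMN2 0.15 (-0.57 after median centring), 4 genes chosen after their values were seen.

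Genes of noradrenergic identity were also lower as a group. Of 20 detected members 7 were lower, 0 were higher and 13 lay in between, with a median of -0.78 at percentile 0.00. SLC18A1, a vesicular monoamine transporter, was at least 3.82-fold lower. The transcription factor gene HAND1 gave -2.59, TH, the rate-limiting enzyme of catecholamine synthesis, -2.04 and the receptor tyrosine kinase gene ALK -1.81. Other transcription factors of the list ranged widely. TFAP2B gave -1.05, PHOX2A -0.92, GATA2 -0.68, GATA3 -0.13, TBX2 -0.12, HAND2 -0.01, ISL1 0.37 (-0.29 after median centring), EYA1 0.50 and SOX11 0.73, and DBH, the enzyme making noradrenaline, gave -1.70. The genes of this last sentence were chosen after their values were seen.

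Detected mesenchymal markers were higher as a group. Of 32 members measured 18 were detected. FN1, CD44, COL1A1 and CAV1, named after their values were seen, were among those not detected on either array. Of the 18 detected members 10 were higher, 2 were lower and 6 lay in between, and the median of 1.34 stood at percentile 100. IL13RA1 was at least 6.22-fold higher, SNAI2 at least 3.04-fold, the collagen gene COL5A1 at least 2.42-fold and ANXA1 at least 1.21-fold. Members that were lower, chosen after their values were seen, were S100A6 at -1.66 and COL6A1 at -1.004. Other members with high signals on both arrays, chosen likewise, were VIM at 0.35 (of opposite sign after median centring), LGALS1 at -0.16, TIMP1 at -0.59 and ANXA2 at 1.30. With undetected sides at their bounds 9 members were higher and the median was 0.82, at percentile 100. Over members detected on both arrays, which leaves out those detected on one array only, it was 0.27, at percentile 89.8, inside the central 95% of random lists.

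The extracellular matrix list, which shares collagen genes and SPARC with the mesenchymal list, had 11 of 22 detected members higher, 3 lower and 8 in between, with a median of 0.99 at percentile 100 and of 0.84 with undetected sides at their bounds, where 10 were higher and 2 lower. The adhesion gene CDH11 gave 1.81 and SPARC, a matrix glycoprotein, 1.54, while the basement membrane collagen gene COL18A1 was at least 1.74-fold lower. The BMP and SMAD list had 6 of 16 members higher, 1 lower and 9 in between, with a median of 0.85 at percentile 99.95 and of 0.59 at the bounds, where 4 were higher. The receptor gene TGFBR2 gave 1.72 and the BMP-responsive homeobox gene MSX1 1.52, BMPR2 was at least 1.52-fold higher, and PMEPA1, an inhibitor of TGF-beta signalling, gave -1.45. Other members, chosen after their values were seen, differed less. SMAD6 gave 1.13, SMAD5 1.03, ID3 0.57, ID1 0.20, ATOH8 0.18, SMAD7 0.07 and BAMBI -0.53. The rest of the detected members, as measured and without allowance for an undetected side, were TGFBI at 1.16, ID2 at 0.92, DLX3 at 0.92, SMAD9 at 0.78 and SMAD4 at 0.65.

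**Figure D2:**
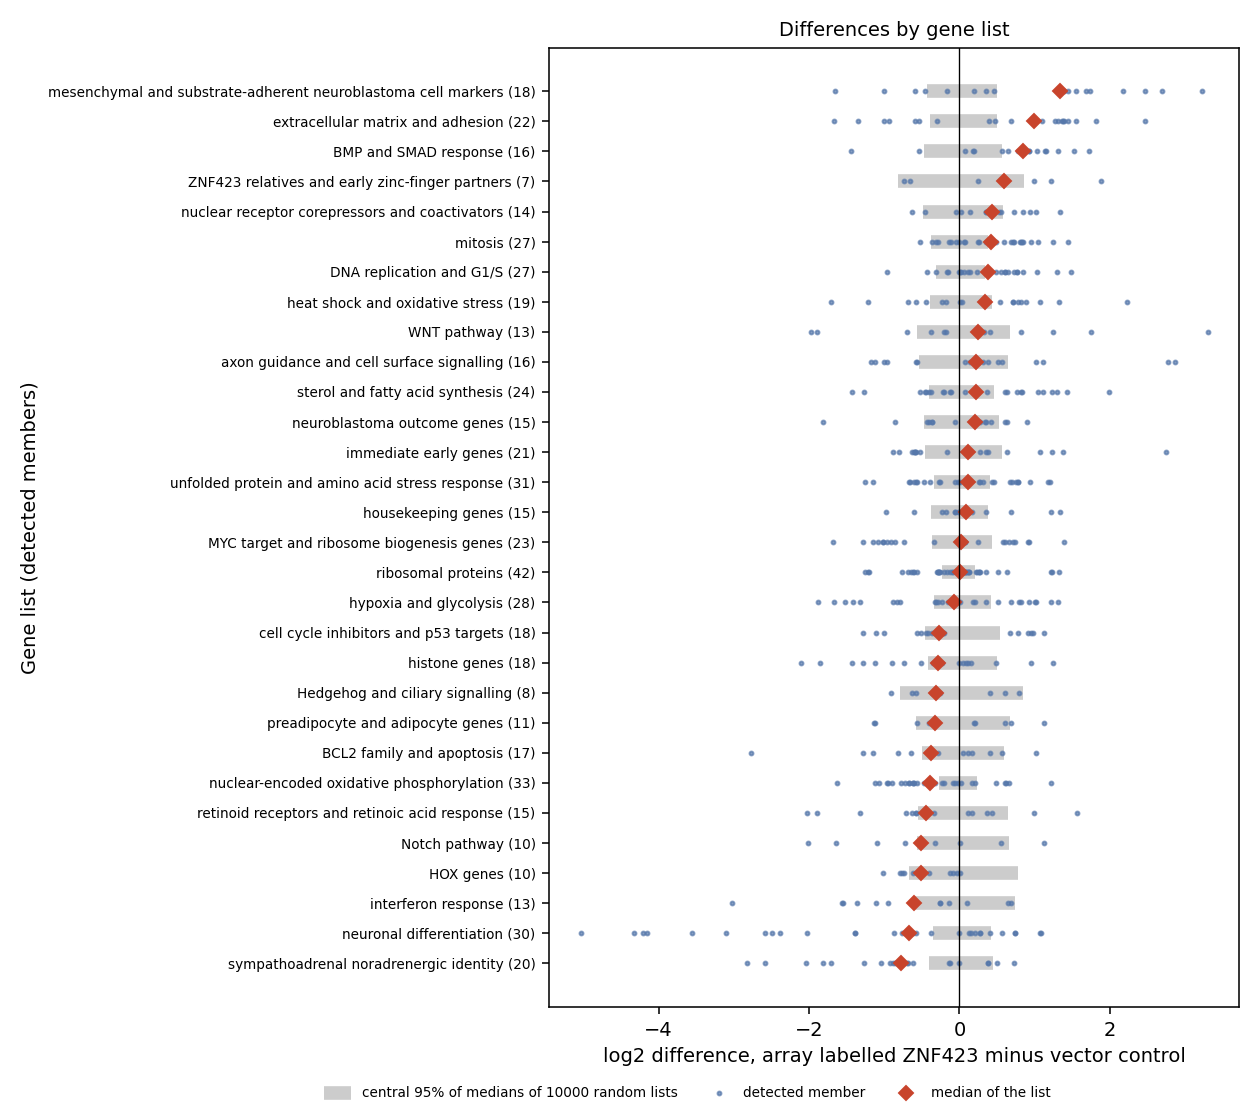
Log2 difference, array labelled ZNF423 minus vector control (x axis), for each gene list with at least 5 detected members (y axis, number detected in brackets). Small points are detected genes, diamonds the list medians and grey bars the central 95% of medians of 10000 random lists of the same size and level; the mesenchymal median is 1.34 (0.82 with undetected sides at their bounds, where the matrix median is 0.84) and the noradrenergic median -0.78.

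Proliferation genes stood slightly above the random lists. The DNA replication list had 3 of 27 members higher, 0 lower and 24 in between, with a median of 0.38 at percentile 98.4. RRM2, a ribonucleotide reductase subunit, gave 1.49, MCM6 1.30, CDK6 1.03 and E2F2 -0.96. After median centring the list's median was -0.034, below 0, at percentile 98.3. The median lay inside the central 95% in the authors' table (percentile 96.2), with no detection filter (97.2) and against random lists not matched on level (93.1). The mitosis list likewise had 3 of 27 higher, 0 lower and 24 in between, with a median of 0.42 at percentile 98.3, and lay inside the central 95% with the trend on gene span removed (0.31, percentile 96.5) and against unmatched random lists (95.2). It was led by the spindle genes NUSAP1 at 1.44, TPX2 at 1.24 and KIF11 at 1.04 and by TOP2A at 0.95.

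The nuclear-encoded oxidative phosphorylation genes were lower by small amounts. Of 33 detected members 3 were lower, 1 was higher and 29 lay in between, with a median of -0.40 at percentile 0.16. The ATP synthase gene ATP5MC1 gave -1.63, COX5B -1.12, NDUFA1 -1.07 and UQCRC2 1.21. Across the 9149 detected genes with a known genomic span, the difference followed gene length: its Spearman correlation with span was 0.33 over genes, which are not independent replicates, and the median ran from -0.43 in the fifth of genes with the shortest span to 0.43 in that with the longest. With a smooth trend on span removed, the medians were -0.42 for the neuronal list, -0.78 for the noradrenergic, 1.11 for the mesenchymal, 0.60 for the matrix and -0.21 for the oxidative phosphorylation list.

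Interferon response genes had 5 of 13 members lower, 0 higher and 8 in between, with a median of -0.60 at percentile 2.28. OAS1 was at least 3.43-fold lower, IFI27 at least 1.64-fold lower, ISG20 gave -1.54 and ISG15 -1.36. At their bounds 4 members were lower. In 6 of 15 alternative settings this list's median lay inside the central 95% of random lists. They were no normalization and median centring (percentile 5.36 each), loess (3.34), a detection p under 0.05 (16.3) and no detection filter (41.3). The sixth was removal of the trend on gene span (-0.37, percentile 10.2).

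ZNF423 has been linked to retinoic acid receptors, and the retinoid list was among those inside that range. Of its 15 detected members 3 were lower (2 at the bounds), 1 was higher and 11 lay in between, with a median of -0.44 at percentile 6.36. The receptor tyrosine kinase gene RET gave -2.03, STRA6, a retinol transporter, -1.32, TGM2 was at least 1.55-fold lower and MEIS2 at least 2.94-fold higher. The nuclear receptor corepressor and coactivator list had a median of 0.44 at percentile 92.9, with 2 of 14 higher, 0 lower and 12 in between, EZH2 at 1.33 (detected probes 1.01 to 1.82), NCOA1 at 1.02 and HDAC2 at 0.85. MED1 was not detected on the control array and has no fold. The list of EBF factors and olfactory neuron genes had only 3 detected members, with 2 lower and 1 in between and a median of -2.77 at percentile 0.17. EBF3 is the only EBF factor among them, and the median is its own value, with EBF3 undetected on the array labelled ZNF423. With undetected sides at their bounds the median was -1.86, in the authors' table -1.56, and with no detection filter -0.079 at percentile 7.58. OLFM1 was at least 5.32-fold lower, EBF3, an EBF factor of the family ZNF423 binds, at least 3.64-fold lower, and ADCY3 gave -0.56. The list of ZNF423 relatives and partners had a median of 0.59 at percentile 87.9, with 2 of 7 higher (1 at the bounds), 0 lower and 5 in between. These 7 include ZNF423 itself, at -0.74 from the brighter of its 2 opposed probes, the other being at least 2.80-fold higher. ZNF521, named after the detection calls were seen, was not detected on either array. ZEB1 was at least 1.15-fold higher, ZEB2 at least 2.19-fold higher, and ZNF217 gave 0.99.

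Markers of other cell types were detected for few genes. The epithelial and endothelial list had 4 detected members, 0 higher, 1 lower and 3 in between, with a median of -0.87 at percentile 4.48. Its keratin gene KRT19 gave -1.76 and ENG -0.77, and PECAM1 was at least 1.57-fold lower. VWF was not detected on the control array and has no fold. The lymphoid and myeloid list had 3 detected members, all within 1 log2 unit, with a median of 0.26 at percentile 50.8 and of 0.0 with undetected sides at their bounds. CD68 gave -0.26 and, at its other detected probe, 0.77, and CD14 and LYZ were not detected on the control array and have no fold. Of the Schwann cell and melanocyte markers 2 were detected, too few for a median, with PMEL at -0.78 and MITF at -0.01.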

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

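The tests of mixed cells, fibroblasts, gene span and the ZNF423 probes in this part were chosen after seeing the data. Of the 6 scaling and background settings only the one without background correction was, though the use of all 6 as a test was decided after the result was seen. For gene span alone the outcome that would count either way was written before the test was run. Among the probes without a gene name, which no comparison uses, 320 were detected on the array labelled ZNF423 and not on the control array, against 85 the other way. Named genes show an excess in the same direction, 1009 against 347, so the direction is not particular to unnamed probes. The excess is larger among the unnamed probes, but probes are set against genes here and the difference was not tested. Unnamed probes at least 1 log2 unit apart are balanced, 196 higher and 200 lower. That balance was counted after quantile normalization, which gives both arrays one distribution, so it does not weigh against the excess in detection.

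Neuronal and noradrenergic genes were lower on the array labelled ZNF423. RNA of other cells that expressed none of these genes would lower all members by about one factor. Yet 31 of the 50 detected members of the 2 lists lay above -1, 15 of them above 0, while the fifth lowest stood at -3.56. Such a dilution alone does not give this spread. Mixed cells that expressed some of these genes would lower members unequally, so they are not excluded. The limits of this test were set after the values were seen. The trend with gene span does not account for the whole of it either: after its removal the higher of the 2 percentiles was 0.71. Under 6 other scalings and background settings that percentile was at most 0.06. A factor common to all genes cancels in such a percentile, so it tests only scaling that depends on level. The medians themselves stayed below 0 under all 6. They came nearest to it without normalization, at -0.40 (neuronal) and -0.60 (noradrenergic). Mixed cells that expressed some of these genes, ZNF423 and any other difference between the 2 cultures stay open. With 1 array per group they cannot be separated.

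Mesenchymal and matrix genes were higher as groups among those detected. Fibroblasts in the culture were tested first by the median difference of 19 transcripts abundant in fibroblasts, which was 0.0 and decides nothing, since the members not detected on either array were entered as 0; the test was then replaced by a count of detected transcripts, with its limits set once the detection calls were known. By that count 9 of the 19 were not detected on the array labelled ZNF423, among them FN1, COL1A1, THY1 and CAV1. Another 5 were higher by at least 1 log2 unit. The limit was set on calls already known, and no array here shows that the undetected probes can read their transcripts. The 19 do not include DCN or LUM. The count therefore does not decide whether fibroblasts are the source of the DCN difference of 5.35. Fibroblasts, other mesenchymal cells and a change within SH-SY5Y cells stay open. After removal of the span trend the lower percentile was 99.82, and under the 6 other scalings 99.99. A factor common to all genes cancels in these percentiles too. Under those scalings both medians stayed above 0. The lowest were 0.96 for the mesenchymal list (median centring) and 0.62 for the matrix list (authors' table). With undetected sides at their bounds the mesenchymal median was 0.82, at percentile 100.

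The 2 ZNF423 probes disagreed. One was at least 2.80-fold higher on the array labelled ZNF423 (1.61 as measured, with the control side not detected), and the other gave -0.74. If both probes read the vector's transcript, exchanged labels would make both lower, which the higher probe goes against, and correct labels would make both higher, which the lower probe goes against. Whether both do is not known, since the probe positions and the insert were not used here. A probe outside the insert reads the cell's own gene and may go either way, so neither exchanged labels nor a probe outside the insert is excluded by these values.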

How the results depend on the processing

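No background correction, bounds for undetected sides and removal of the gene span trend were chosen after seeing the data. Of 15 settings tried per list, all kept the neuronal, noradrenergic, BMP, matrix and oxidative phosphorylation medians outside the central 95% of random lists on the main side, as did 14 for the mesenchymal, 13 for mitosis, 12 for replication and 9 for interferon. Of 154 named genes no difference of 1 log2 unit or more changed sign in the settings run on them. These settings reprocess the same 2 arrays, and most named genes were chosen for large differences, so sign changes were unlikely. Of 1078 values under these settings 272 moved by more than the SD of 0.38 between probes of one gene. Quantile normalization as an alternative was not run, since it is the main setting. No paired analysis was possible because each group has 1 array. Signal over background limits the low end: the 3052 genes of lowest level held 519 of the higher and 483 of the lower genes. Where no cause is given, the cause was not tested.

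Genes higher numbered 680 with detection on both arrays (fewer genes tested), 2174 without normalization, 443 in the authors' table, 527 without background correction, 2567 at 1.5-fold and 223 at 3-fold. Genes lower numbered 588 without normalization, 545 in the authors' table, 614 without background correction, 2197 at 1.5-fold and 346 at 3-fold. Genes shared with the main counts were 1061 higher and 564 lower without normalization, and 441 and 540 in the authors' table. The higher ZNF423 probe gave 2.01 without normalization, 1.04 in the table and 1.12 without background correction. The lower gave -0.34 without normalization, and the mean of the probes 0.44.

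The mean over members was -1.17 for the neuronal, 0.64 for the BMP and 0.56 for the matrix list. Median centring gave -1.03 for the noradrenergic, 0.55 for the BMP, -0.034 for the replication (below 0) and -0.99 for the oxidative phosphorylation list. Loess gave 0.56 for BMP. At a detection p under 0.05 the mesenchymal median was 0.65, the BMP 0.57 and the matrix 0.51, and with no filter 0.24, 0.19 and 0.18, with interferon at -0.018. Detection on both arrays gave the mesenchymal list 0.27. Bounds gave it 0.82 and BMP 0.59. The authors' table gave BMP 0.55 and matrix 0.62, and no background correction BMP 0.60. Without normalization mitosis stood at 0.74, interferon at -0.16 and oxidative phosphorylation at -0.56. With the span trend removed matrix stood at 0.60 and oxidative phosphorylation at -0.21.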

Other observations

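Several further gene groups held members that differed while their medians lay inside the central 95% of random lists, and the sign of a median near 0 is not fixed across scalings. Among WNT genes 3 of 13 were higher (2 at the bounds), 2 lower and 8 in between (median 0.24, percentile 69.5). Next to DKK2, WNT5A was at least 1.05-fold higher, the WNT antagonist SFRP1 gave -1.97 and AXIN2, a target of canonical WNT signalling, was at least 3.56-fold lower. Notch genes had 1 of 10 higher, 3 lower (2 at the bounds) and 6 in between (median -0.52, percentile 3.74), with DLL3 at -2.02, NOTCH3 at -1.64, RBPJ at 1.12 and NOTCH4 at least 1.42-fold lower. Axon guidance genes had 4 of 16 higher, 3 lower and 9 in between (median 0.23, percentile 66.5), with SEMA3C at least 3.12-fold higher beside its receptor gene NRP1, and SEMA3F at -1.17 and PLXNA2 at -1.12. HOX genes had 0 of 10 higher, 1 lower (0 at the bounds) and 9 in between (median -0.52, percentile 6.34), with HOXC5 at least 1.44-fold and HOXD3 at least 1.54-fold lower, HOXC6 at -0.77 and HOXC4 at -0.74. Hedgehog genes had all 8 in between (median -0.31, percentile 18.9), with HHIP at -0.91 and SMO at -0.64, IFT88 at least 1.44-fold higher and GAS1 at least 1.16-fold higher. Adipocyte genes had 1 of 11 higher, 2 lower and 8 in between (median -0.33, percentile 13.4), with KLF15 at -1.13, CEBPD at -1.13 and PLIN2 at 0.68. The 1 counted as higher, PPARGC1A, was not detected on the control array and has no fold, so 0 were higher at the bounds. Immediate early genes had 4 of 21 higher, 0 lower and 17 in between (median 0.12, percentile 57.8), with SPRY1 at 2.74 (detected probes 1.41 to 2.79), KLF2 at 1.37, CCN1 at 1.23 and KLF6 at 1.07. Neuroblastoma outcome genes had 0 of 15 higher, 1 lower and 14 in between (median 0.20, percentile 77.5), with CAMTA1 at 0.89, LMO1 at -0.86 and BARD1 at 0.64.

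Stress and metabolic groups also went both ways. In the heat shock and oxidative stress list 3 of 19 were higher, 2 lower and 14 in between (median 0.34, percentile 94.9): NQO1, a quinone reductase, gave 2.22 and TXNRD1 1.33, while the metallothionein genes MT1X and MT2A gave -1.71 and -1.22. Sterol and fatty acid synthesis had 6 of 24 higher (5 at the bounds), 2 lower and 16 in between (median 0.22, percentile 82.5), with MSMO1 at 1.99, INSIG1 at 1.29, CYP51A1 at least 1.92-fold higher and SREBF1 at least 2.63-fold lower. Hypoxia and glycolysis had 4 of 28 higher (3 at the bounds), 5 lower and 19 in between (median -0.07, percentile 29.5), with ANKRD37 at -1.87, ADM at -1.67, PFKFB4 at -1.52 and VEGFA at -1.42. The unfolded protein list had 2 of 31 higher, 2 lower and 27 in between (median 0.11, percentile 68.4), with PSAT1 at 1.21, HSPA5 at 1.18, SDF2L1 at -1.26 and CALR at -1.15. Apoptosis genes had 1 of 17 higher, 3 lower (2 at the bounds) and 13 in between (median -0.37, percentile 8.66), with HRK at least 4.72-fold and BCL2L11 at least 1.56-fold lower, BAX at -1.29 and BNIP3 at 1.02. Cell cycle inhibitors and p53 targets had 1 of 18 higher, 3 lower (2 at the bounds) and 14 in between (median -0.28, percentile 13.0), with TP53INP1 at 1.12, PHLDA3 at -1.003 and CDKN2A at least 1.54-fold lower. MYC target and ribosome biogenesis genes had 1 of 23 higher, 6 lower (5 at the bounds) and 16 in between (median 0.03, percentile 53.4), with RRP9 at -1.68, EIF4EBP1 at -1.28, NOP16 at -1.15 and POLR1B at least 2.44-fold higher. Histone genes had 1 of 18 higher, 5 lower and 12 in between (median -0.29, percentile 9.52), with H2AC18 at -1.85, H1-2 at -1.43, H1-10 at -1.29 and H2BC9 at least 3.85-fold lower. Ribosomal protein genes had 3 of 42 higher (2 at the bounds), 3 lower and 36 in between (median 0.01, percentile 52.4), with RPL34 at -1.26 (-0.68 at its other detected probe), RPS23 at 1.23, RPL22 at 1.21 and RPL37 at least 1.503-fold higher. Housekeeping genes had 2 of 15 higher, 0 lower and 13 in between (median 0.09, percentile 71.1), with TFRC at 1.33, YWHAZ at 1.22 (0.35 at its other detected probe), POLR2A at -0.97 and B2M at 0.68.

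A hypothesis was that the lower oxidative phosphorylation genes, which are short, only follow the trend with gene span. Removal of the trend was chosen after seeing the data, and the outcome that would count either way was written before that test was run. With the trend removed the list's median went from -0.40 to -0.21 and stood at percentile 1.08, still outside the central 95%, so the span trend may account for part of the difference and not for the whole. Whether the trend itself reflects RNA quality, labelling or the cells was not tested.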
